A study of Homo sapiens with 9 samples.

How the data were processed

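RNA was measured in 5 primary Group 3 medulloblastomas and in 4 libraries of the D341 cell line, 2 with a hairpin against GFP and 2 with 1 hairpin against OTX2. Per the labels, libraries were made from ribosomal-RNA-depleted total RNA with a stranded, random-primed kit, so nuclear, unspliced and small structural RNAs are part of them. Read counts per gene symbol were deposited for the 4 D341 libraries; the authors' notes name STAR, HTSeq and human genome build hg19, without versions, annotation or strand setting. FPKM values for all 9 samples were also deposited by the authors, whose notes name Cufflinks as well, and they were used on the authors' scale. Neither table was recomputed from reads. No coordinates are given, and neighbouring genes were found by name in the RefSeq table of GRCh38.p14.

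Library totals were 29194300 and 32798349 counts for shGFP and 21688933 and 23709390 for shOTX2, and 3 counts correspond to 0.103, 0.0915, 0.138 and 0.127 CPM in that order. The depth of the tumours is unknown. Samples were grouped by label. Shared replicate numbers were not taken as pairs, a choice made in advance because a replicate term uses up residual degrees of freedom, of which there were 2. Deviations of equally numbered libraries, looked at after the fit, had a correlation of 0.108. The spread between libraries of a group exceeded counting noise, with a chi-square per gene of 20.1 for shGFP and 17.5 for shOTX2, and the biological coefficient of variation was 11.4%.

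In D341, shOTX2 was compared with shGFP by the edgeR quasi-likelihood test with TMM normalization and the filterByExpr filter, which kept 13592 of 27081 genes. The tumours were compared with D341 by limma with a trended prior on log2(FPKM + 1) for 14319 genes with at least 1 FPKM in 1 sample, the 2 shGFP libraries averaged to 1 sample because D341 is 1 line. FPKM of symbols on several lines of the table (647 of 26963) were summed. P values were 2-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. In all, 28 gene lists were fixed in advance: photoreceptor and pineal, neural and retinal transcription factors, neuronal structure, axon guidance, replication, mitosis, MYC-responsive growth, p53 targets, interferon response, ATF4 and unfolded protein response, glycolysis and hypoxia, Notch, extracellular matrix, Polycomb and Trithorax, replication-dependent histones, small structural RNAs, markers of the 4 medulloblastoma subgroups and of 8 other cell types. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. The preset was chosen because few residual degrees of freedom, 2 in D341, give a poor estimate. With an estimated correlation camera also takes its p value from those few degrees of freedom, so lists can seldom pass. For the genes called with a log2 fold change of at least 1, the median log2(FPKM + 1) in each tumour was compared with 10000 random lists matched in 20 bins of D341 level, and the 5 differences were tested by an exact sign-flip permutation.

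The fixed genes and lists and the tests, filters and alternatives of the comparisons were chosen before the data were examined, apart from 2 added alternatives. The closing section names these and the tests chosen later. Named in every case were 12 genes (OTX2, CRX, NRL, NEUROD1, MYC, MYCN, NEK2, GFI1, GFI1B, EOMES, EZH2 and PAX6). Also named were the 10 largest called differences each way with a mean of at least 5 CPM or 5 FPKM and groups that do not overlap, up to 4 called members of each list with the smallest adjusted p, and the subgroup markers. Of the genes this rule selects, 2 are not reported here. Clone-style and small RNA symbols were counted but not named, and sex-linked marker genes were left out. Nuclear RNAs, symbol families with at least 10 members, neighbouring genes and any gene described as picked after the values were seen fall outside that rule.

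Alternatives were other normalizations (RLE, upper quartile, quantile), other filters, other tools (DESeq2, limma-voom, limma on FPKM), a replicate term, a pseudocount of 0.1, other thresholds, and leaving out each library or tumour. The authors' FPKM for the 4 D341 libraries carried a median shift of -0.19 on the log2 scale. The workflow was tested on simulated data built from these tables: of 200 changed genes 42% were recovered at 1.5-fold, 80% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 12 of 13259 unchanged genes called. For the tumours 2%, 4%, 60% and 86% were recovered at log2 shifts of 1, 2, 4 and 6, with 6 of 14119 unchanged genes called, so differences of 2 log2 units are mostly missed. The D341 simulation changed 200 genes while 5288 were called in the data, so its recovery rates need not hold there. Matched random lists gave -0.00891 for an unchanged list and 0.491 for one raised by 0.5. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. Reads, splicing and variants were not analysed here.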

Results

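Gene expression was measured by RNA sequencing of ribosomal-RNA-depleted total RNA in 9 samples. 5 samples were primary Group 3 medulloblastomas, here called tumours 1 to 5, and 4 were libraries of D341, an established cell line of the same tumour subgroup. D341 cells carried a lentiviral short hairpin against GFP, the control (shGFP, 2 libraries), or against OTX2 (shOTX2, 1 hairpin, 2 libraries). OTX2 encodes a homeodomain transcription factor of the developing forebrain, midbrain and retina. Read counts per gene were analysed for the 4 D341 libraries, whose totals were 29194300 and 32798349 reads for shGFP and 21688933 and 23709390 for shOTX2. Each tumour was measured once and was analysed as FPKM (fragments per kilobase of transcript, scaled to library size), so its depth in reads is unknown.

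The D341 comparison asked which RNAs change when OTX2 is depleted. The OTX2 level was 975 and 1006 CPM (counts scaled to library size) in the shGFP libraries and 805 and 736 CPM in the shOTX2 libraries, so that the mean fell by 22.2% (log2 fold change -0.36, SE 0.12, adjusted p = 0.0229, edgeR, Benjamini-Hochberg, n = 2 per group). Of 40 genes of neuronal structure and synapse 28 rose, among them DCX, a microtubule-binding protein of migrating neurons, from 0.26 ± 0.03 to 18.5 ± 1.34 CPM (SD, n = 2). Of 31 photoreceptor and pineal genes 20 fell, among them PDE6A, the rod phosphodiesterase that responds to light, from 29.3 ± 0.40 to 3.73 ± 1.39 CPM. Genes of DNA replication, mitosis and the replication-dependent histones fell nearly throughout their lists, and genes of the glycolysis and hypoxia list and of the ATF4 and unfolded protein list fell in smaller shares. Of 13592 genes tested, 5288 changed (38.9%), with 2812 lower and 2476 higher. The change was at least 2-fold for 853 of the lower and 796 of the higher genes, and at least 4-fold for 181 and 198.

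Among the largest falls, TTR, the thyroid hormone and retinol carrier made by choroid plexus, was 28.0-fold lower, and ERMN, a cytoskeletal protein of oligodendrocytes, was 15.3-fold lower. NEB, the giant thin-filament protein of muscle, had a log2 fold change of -3.90. DOCK8, an activator of small GTPases, went from 363 ± 7.70 to 30.9 ± 22.6 CPM. FMO2 (a flavin-containing monooxygenase), MCHR1 (a melanin-concentrating hormone receptor), SRPX, NIPAL1 and PDE6A had log2 fold changes between -3.65 and -2.96. Among genes with a mean of at least 5 CPM, the largest rises beside DCX were those of NPPA, the precursor of atrial natriuretic peptide, at 63.5-fold from 2 and 8 reads to 274 and 208, and of CHRNA3, a nicotinic acetylcholine receptor subunit, at 22.1-fold. KIF5C, a neuronal kinesin, rose 21.1-fold and SCN3A, a voltage-gated sodium channel, 19.4-fold. CDH12, SULF2, CABP7, PPP1R17 and SEZ6L had log2 fold changes of 3.45 to 3.09, and SEZ6L, a membrane protein of neurons, reached 428 ± 46.6 CPM. Adjusted p values of these genes lay between 4.98e-12 and 5.19e-07.

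**Figure D1:**
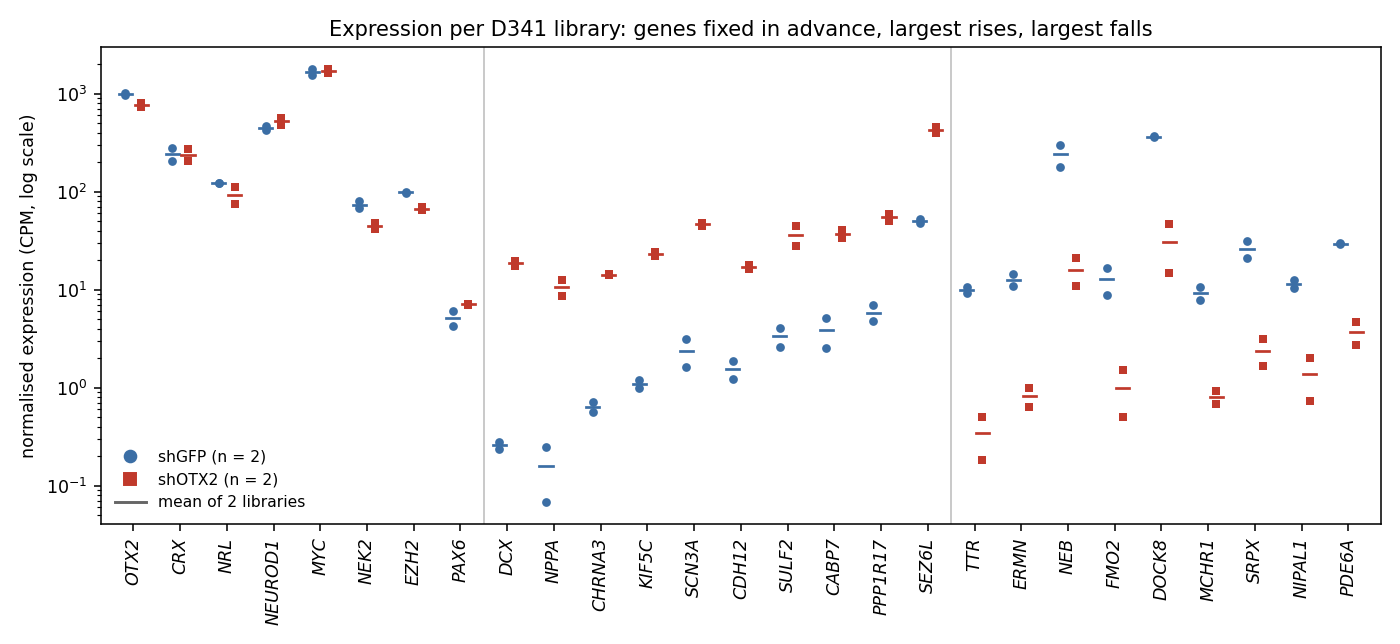
Normalised expression (CPM, log scale) of 8 genes fixed in advance and genes among the largest rises and falls in each D341 library; circles are shGFP, squares shOTX2 and bars the mean of 2 libraries. DCX rises from 0.26 to 18.5 CPM and PDE6A falls from 29.3 to 3.73 CPM, while OTX2 moves from a mean of 991 to 771 CPM.

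The other genes fixed in advance moved little or in part. MYC, the growth-promoting transcription factor, stood at 1660 and 1706 CPM before and after depletion (log2 fold change 0.04, SE 0.13, adjusted p = 0.836), and the photoreceptor regulator CRX at 241 and 239 CPM (-0.01, SE 0.14, adjusted p = 0.951). Leaving out 1 library moved MYC between -0.04 (without shGFP library 2) and 0.14, and CRX between -0.24 and 0.24 (without shGFP library 2), so neither has a direction here. NEUROD1, a neurogenic transcription factor, had a log2 fold change of 0.23 (adjusted p = 0.143) and PAX6, a regulator of eye and brain development, of 0.46 (adjusted p = 0.129). NEK2, a mitotic kinase, fell by 0.73 on the log2 scale (adjusted p = 0.000204) and EZH2, the Polycomb methyltransferase, by 0.56 (adjusted p = 0.000771). NRL, the rod transcription factor, fell by 0.39 (adjusted p = 0.0346), a call that was lost without shGFP library 1 (adjusted p = 0.258), shGFP library 2 (0.248) or shOTX2 library 1 (0.639, log2 fold change -0.12). MYCN, the neural relative of MYC, had 1 and 0 reads in shGFP and 11 and 13 in shOTX2, a rise by a ratio of 32.8 in reads per total (95% exact Poisson interval 5.34 to 1350, for counting error alone), whose call was lost without shGFP library 2 (adjusted p = 0.0519). GFI1 had 5, 5, 5 and 1 reads, EOMES 1, 2, 2 and 0, and GFI1B none, below what these totals can compare, since 3 reads amount to 0.0915 to 0.138 CPM.

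Of the 31 tested genes of the photoreceptor and pineal list, 20 fell and 2 rose, and 21 and 2 when adjusted over the list alone (median log2 fold change -1.35, camera adjusted p = 1.5e-12, adjusted p = 0.407 with an estimated correlation). ABCA4, the retinal transporter of photoreceptor discs, fell by 2.71, GUCA1A, an activator of guanylate cyclase, by 2.74, and ASMT, the last enzyme of melatonin synthesis, by 2.32. Neural and retinal transcription factors moved both ways, with 16 higher and 7 lower of 41, or 17 and 8 adjusted over the list alone (median 0.28, adjusted p = 0.00151, adjusted p = 0.407 with an estimated correlation). The proneural factor NEUROD4 rose by 2.47, the neurogenic zinc finger MYT1 by 2.12 and NHLH1 3.02-fold. In the neuronal structure and synapse list, 28 of 40 genes rose and 1 fell, or 28 and 2 adjusted over the list alone (median 1.06, adjusted p = 2.32e-22, adjusted p = 0.144 with an estimated correlation). MAP2, a dendritic microtubule protein, rose from 16.5 ± 2.18 to 120 ± 4.06 CPM, the adhesion molecule L1CAM from 42.9 ± 2.42 to 200 ± 16.9 and the granule protein CHGA from 36.1 ± 0.95 to 153 ± 5.63. Axon guidance genes were split, with 17 higher and 13 lower of 52 both over all genes and adjusted over the list alone (adjusted p = 0.211). The receptor EPHA4 rose by 2.57 and the semaphorin SEMA6A by 2.10. Without shOTX2 library 1 this list passed the threshold as higher (adjusted p = 0.0386). RNAs taken as markers of the nucleus were looked at after the values were seen, and 5 of 7 rose in the shOTX2 libraries. MALAT1 rose by 1.36, NEAT1 3.03-fold, KCNQ1OT1 by 1.65, MIAT by 1.87 and TUG1 by 0.29, while PVT1 (0.25) and OIP5-AS1 (-0.11) were not called.

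Among DNA replication genes, 47 of 50 fell and none rose, or 48 adjusted over the list alone (median -0.98, adjusted p = 6.18e-23, adjusted p = 0.407 with an estimated correlation). PRIM1, the primase subunit, went from 78.1 ± 10.6 to 27.1 ± 5.33 CPM and RRM1, the large subunit of ribonucleotide reductase, from 250.2 ± 11.4 to 102 ± 27.1. In the mitosis list 47 of 54 fell and none rose, the same count as adjusted over the list alone (median -0.68, adjusted p = 1.18e-18, adjusted p = 0.407 with an estimated correlation). The spindle checkpoint target CDC20 was 2.83-fold lower, while the mitotic kinase PLK1 fell by 1.46 and the transcription factor FOXM1 by 1.37. All 31 tested replication-dependent histone genes fell, over all genes and adjusted over the list alone (median -1.43, adjusted p = 2.4e-35, adjusted p = 0.407 with an estimated correlation). HIST1H4B fell by 2.39 and HIST1H3J by 1.84. Of 50 genes of MYC-responsive growth and ribosome production 21 fell by both counts, those over all genes and adjusted over the list alone (median -0.25, adjusted p = 0.000142, adjusted p = 0.407 with an estimated correlation), with LDHA, lactate dehydrogenase, at -1.11 and the ribosome biogenesis factor RRP9 at -0.89. Glycolysis and hypoxia genes fell in 19 of 30 cases and rose in 1, by either adjustment, over all genes or adjusted over the list alone (median -0.69, adjusted p = 6.08e-08, adjusted p = 0.407 with an estimated correlation). The glycolytic enzyme PGAM1 fell by 1.86, the glucose transporter SLC2A1 by 1.23 and the hypoxia-induced NDRG1 by 2.43. In the ATF4 and unfolded protein list 19 of 38 fell and 2 rose, or 20 and 2 adjusted over the list alone (median -0.43, adjusted p = 0.000142, adjusted p = 0.407 with an estimated correlation). Its falling members included the amino acid transporter SLC7A5 (-1.33) and the serine pathway enzyme PHGDH (-1.03), while the 2 that rose, named after their values were seen, were the chaperone HSPA5 (0.47) and SEL1L (0.40), which serves degradation in the endoplasmic reticulum.

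The remaining lists went both ways. Of 33 p53 target genes 10 fell and 6 rose, or 11 and 7 adjusted over the list alone (adjusted p = 0.651), with the apoptosis inhibitor TRIAP1 at -1.23 and TP53INP1 at 0.95. Interferon response genes fell in 10 of 29 cases and rose in 3, or 10 and 4 adjusted over the list alone (adjusted p = 0.0516), and IFITM1 fell by 1.42 and GBP1 by 1.70. The interferon list passed the threshold as lower without shOTX2 library 2 (adjusted p = 0.0408), with RLE size factors (0.0482), with the filter of at least 1 CPM (0.00471) and without small RNAs, ribosomal proteins and MALAT1 (0.044), over a range of 0.00471 to 0.92 in 10 alternatives. For neural progenitor and Notch genes 9 of 31 fell and 7 rose, or 10 and 8 adjusted over the list alone (adjusted p = 0.978), and the median (-0.08) and test pointed down while the mean (0.08) pointed up. ID4 rose by 2.35 and HEY1 by 1.68, whereas the receptor NOTCH2 fell by 0.97. The extracellular matrix list had 12 higher and 9 lower of 35, or 13 and 11 adjusted over the list alone (adjusted p = 0.895), including the laminin LAMA1 at -2.24 and the transcription factor ZEB1 at 0.79. Without shOTX2 library 1 it passed the threshold as higher (adjusted p = 4.23e-08). Polycomb and Trithorax genes had 12 higher and 7 lower of 40 by either adjustment, over all genes or adjusted over the list alone (adjusted p = 0.187), with JARID2 at 0.76 and SUZ12 at -0.68, and passed as higher without shOTX2 library 2 (adjusted p = 0.0408). Small structural RNAs had 2 lower and 1 higher of 13, or 1 and 1 adjusted over the list alone (adjusted p = 0.664). Those calls were lost without shGFP library 1 for RMRP (adjusted p = 0.349) and SNORD17 (0.0825), without shGFP library 2 for SNORD17 (0.323) and SCARNA7 (0.0584), and without shOTX2 library 1 for RMRP (0.29) and SNORD17 (0.313). The 6 Group 3 markers divided evenly, 3 lower and 3 higher, also adjusted over the list alone (adjusted p = 0.992), with the photoreceptor matrix gene IMPG2 at -1.35 and the natriuretic peptide receptor NPR3 at 0.65. The EYS call was lost without shGFP library 1 (adjusted p = 0.0785) or 2 (0.0713), and that of GABRA5 without shGFP library 2 (0.246) or shOTX2 library 1 (0.212). With limma on FPKM the calls of NPR3 (adjusted p = 0.147), EYS (0.146) and GABRA5 (0.099) were lost. All 3 tested SHH markers fell, adjusted over the list alone too, with HHIP at -2.50 and PDLIM3 at -0.61. The call of SFRP1, at 24 and 29 reads against 1 and 7, was lost without shGFP library 1 (adjusted p = 0.0991), shGFP library 2 (0.114) or shOTX2 library 1 (0.0893) and with DESeq2 (0.0834). The only WNT marker tested, TNC (-0.29), and the only Group 4 marker tested, UNC5D (-0.05), were not called.

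Markers of other cell types followed no single direction. In the astrocyte list 4 of 7 genes fell and 1 rose by either adjustment, over all genes or adjusted over the list alone (median -0.98, adjusted p = 0.0308, adjusted p = 0.437 with an estimated correlation), among them the glutamate transporter SLC1A3 at -1.17 and clusterin, CLU, at -2.07. This call was lost without shOTX2 library 1 (adjusted p = 0.0764) and with no filter on low counts (adjusted p = 0.41), against a range of 0.00414 to 0.41 over 10 alternatives. Granule and Purkinje neuron markers had 3 higher and 2 lower of 7, also adjusted over the list alone (adjusted p = 0.281), with a negative median (-0.17) and a positive mean (0.18) and test. NEUROD2 rose 2.82-fold and the glutamate transporter SLC17A7 by 1.46, whereas CBLN1 fell by 0.95. Pericyte and fibroblast markers had 3 higher and 3 lower of 11, or 3 and 4 adjusted over the list alone (adjusted p = 0.992), and the list passed as higher without shOTX2 library 1 (adjusted p = 0.000808). Single calls were lost without shGFP library 1 for ACTA2 (0.0729), TAGLN (0.0936) and PDGFRB (0.247), without shGFP library 2 for LUM (0.055), TAGLN (0.176) and PDGFRB (0.205), without shOTX2 library 1 for PDGFRB (0.285) and without shOTX2 library 2 for TAGLN (0.151). Of 4 oligodendrocyte markers 2 fell (ERMN and CNP) and 2 rose (OLIG2 and UGT8), also adjusted over the list alone. The UGT8 call was lost without shGFP library 1 (adjusted p = 0.207), shGFP library 2 (0.115) or shOTX2 library 1 (0.313). Of 4 endothelial markers 1 rose (VWF) and 1 fell (EGFL7), or 2 and 1 adjusted over the list alone, and both calls were lost without shGFP library 1 (adjusted p = 0.0571 and 0.083) or shGFP library 2 (0.0784 and 0.0648). None of 2 macrophage markers was called by either adjustment, over all genes or adjusted over the list alone, and no lymphocyte or red cell marker had counts enough to test.

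**Figure D2:**
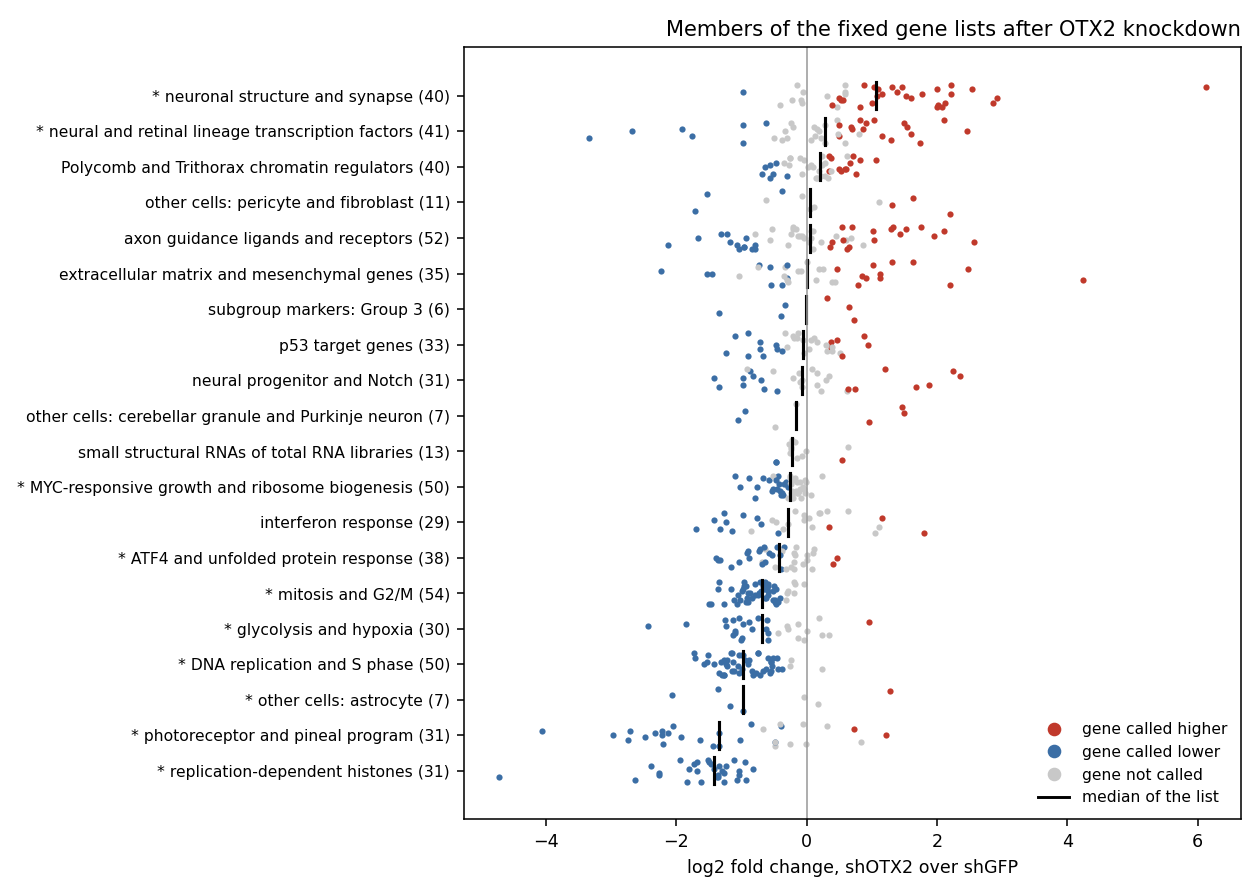
Log2 fold change (shOTX2 over shGFP) of every tested gene in the 20 lists with at least 5 tested members, the number in parentheses; red and blue points are genes called higher and lower, bars are medians, and stars mark lists past the camera threshold. Medians run from -1.43 for replication-dependent histones to 1.06 for neuronal structure and synapse.

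Genes were tested with edgeR and lists with camera at a preset correlation, 10 of 20 lists passing, 8 lower and 2 higher. With an estimated correlation none of the 20 passed, 1 had an unadjusted p under 0.05, and fry called 1, the neuronal list (adjusted p = 0.021). The estimated setting has little power at 2 residual degrees of freedom. For the neuronal list the estimate was -0.0112, below the preset 0.01, yet the camera adjusted p was 0.144. Such failures therefore do not show that correlation between genes accounts for a list. For replication and mitosis the estimates were 0.744 and 0.757, far above the preset, so their preset p values may be too small. Leaving out 1 library changed the number of called genes from 5288 to 2276 (without shGFP library 1), 3019 (shGFP library 2), 2939 (shOTX2 library 1) or 5105 (shOTX2 library 2), with 93 of 109 called named genes keeping their call in every case. The OTX2 call was lost in each case, at adjusted p = 0.0665, 0.0926, 0.094 and 0.16. Those p values lie in a range of 0.00511 to 0.16 over 14 alternatives, and log2 fold changes of OTX2 without 1 library lay between -0.41 and -0.30. Nothing in the labels says whether the libraries of a group came from separate cultures, so all p values measure only the spread between these libraries.

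The next comparison asked how the Group 3 tumours express these genes and where D341 lies outside them. OTX2 was at 264, 128, 278, 120 and 215 FPKM in tumours 1 to 5 and at 295 and 312 FPKM in the D341 shGFP libraries (log2 difference 0.68, SE 0.86, adjusted p = 0.635, limma). MYC stood at 2.12, 14.3, 58.0, 0.41 and 6.77 FPKM in the tumours and at 476 and 424 in D341. EOMES, a T-box factor of glutamatergic progenitors, was at 100 and 29.7 FPKM in tumours 1 and 5 and at 1.34 or below in the others. CRX ranged from 0.60 to 47.0 FPKM, NRL from 3.94 to 129 and NEUROD1 from 2.23 to 16.7 in the tumours, against means of 33.7, 40.6 and 95.1 in D341. MYCN reached 5.39 FPKM in tumour 1 and 4.46 in tumour 5, and NEK2 and EZH2 lay between 0.47 and 15.5 FPKM in the tumours and at 23.3 and 24.1 in D341. PAX6 was below 1 FPKM in every tumour, as were GFI1 and GFI1B.

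Subgroup markers described the tumours. Of the Group 3 markers, IMPG2 had a mean of 134 ± 59.4 FPKM (SD, n = 5), GABRA5, a GABA receptor subunit, 24.3 ± 19.4, EYS, a photoreceptor matrix protein, 56.7 ± 26.1 and NPR3 22.4 ± 31.8, all at 1 FPKM or more in every tumour. MAB21L2 was present in 3 tumours at 3.23 to 61.6 FPKM. Group 4 markers were uneven. In tumours 1 and 5, EOMES was at 100 and 29.7 FPKM and KHDRBS2, an RNA-binding protein, at 46.4 and 52.1. In the other tumours they were at most 1.34 and 6.99 FPKM. UNC5D was at 2.75 to 3.39 in tumours 1, 4 and 5, and KCNA1 at 1.37 or below. RBM24 and OAS1 stayed below 1 FPKM in all 5. The WNT markers WIF1, GAD1, DKK2 and EMX2 were below 1 FPKM throughout, and TNC reached 16.1 in tumour 5. Among SHH markers PDLIM3 (0.40 to 3.63), EYA1 (0.12 to 2.19), HHIP (0.01 to 2.12) and SFRP1 (0.01 to 5.42) were low, and ATOH1 was listed at 0 in all 5 tumours.

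**Figure D3:**
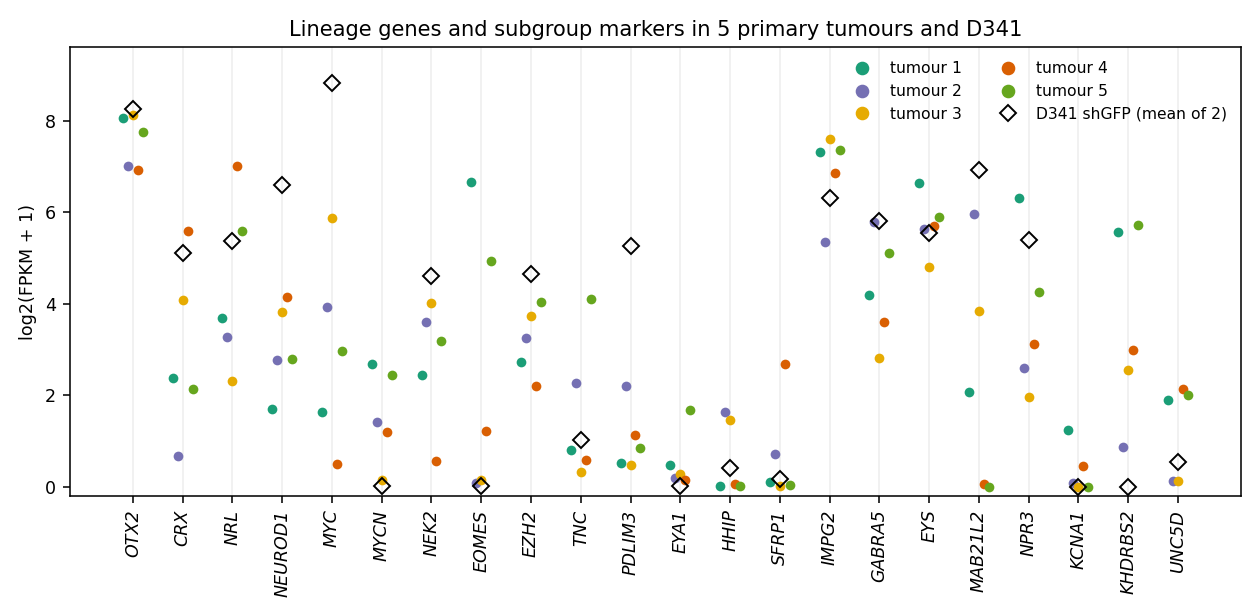
Expression as log2(FPKM + 1) of lineage genes and subgroup markers in each tumour (coloured points) and in D341 (diamonds, mean of 2 shGFP libraries). OTX2 is high in all samples, MYC is highest in D341, and EOMES and KHDRBS2 are highest in tumours 1 and 5.

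Against the spread of the 5 tumours, D341 was higher for 139 genes and lower for 10 of 14319 tested (1.04%), with 2807 at an unadjusted p under 0.05 (limma, Benjamini-Hochberg). The balance of directions depends on the pseudocount, since 0.1 in place of 1 gave 42 higher and 127 lower. ZFP42, a zinc finger of pluripotent cells, was at 43.8 and 47.4 FPKM in D341 and listed at 0 in all 5 tumours, zeros that no counts of the tumours were at hand to check. DCT, a melanin synthesis enzyme, had 50.8 FPKM in D341 and 0.16 ± 0.14 in the tumours (SD, n = 5), the neurofilament NEFH 46.9 and 0.94 ± 0.48, the protocadherin PCDH10 32.7 and 0.37 ± 0.24, and the activin subunit INHBE 21.3 and 0.05 ± 0.02. ARSE, an arylsulfatase, and LINC01021, a non-coding RNA, differed by 5.08 and 4.44 on the log2 scale. These 7 genes kept their call whichever tumour was left out. All 22 other named genes called here lost theirs without tumour 1, and most of them without other tumours too. SLC13A4, a sulfate transporter, was at 157 FPKM in D341 and 1.39 ± 1.63 in the tumours, and the detoxifying enzyme MGST1 at 99.9 and 2.35 ± 2.91. RPS16 was at 691 and 24.5 ± 12.4 FPKM, a value that reads shared with its pseudogenes can alter. In D341 BEX2 (0.73 against 35.6 ± 15.5 FPKM) and BEX4 (0.08 against 25.8 ± 7.03), small adaptor proteins of neurons, were lower, as was MAP2 (1.67 against 33.8 ± 6.03) and CLIP4 (0.43 against 16.5 ± 4.75). ARMCX1, TCEAL7 and the haemoglobin gene HBB were listed at 0 in both D341 libraries, with 0 reads there, and had means of 8.61 ± 1.61, 8.03 ± 2.02 and 83.4 ± 55.7 FPKM in the tumours. The imprinted gene NNAT had 1 and 0 reads in D341 and 17.2 to 60.4 FPKM in the tumours. EEF1A1 was listed at FPKM 0 in both D341 libraries although they held 305839 and 407192 reads of it, so its call rests on a failed estimate.

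Lists showed proliferation above and tissue markers below the tumours in D341. Replication genes were above all 5 tumours in 47 of 50 cases, where chance gives 16.7% and 43.5% of all tested genes lay above, with a mean log2(FPKM + 1) of 4.16 in D341 and 2.39 ± 0.87 in the tumours (SD, n = 5; camera adjusted p = 3.08e-06, adjusted p = 0.581 with an estimated correlation). Mitosis genes were above in 39 of 54 (adjusted p = 0.00596, adjusted p = 0.699 with an estimated correlation), and MYC-responsive growth genes in 50 of 51 (5.87 against 3.57 ± 0.78, adjusted p = 4.42e-10, adjusted p = 0.444 with an estimated correlation). No single member of these 3 lists was called over all genes, and 0, 0 and 24 were higher when adjusted over the list alone. p53 targets were also higher (adjusted p = 1.29e-05, adjusted p = 0.444 with an estimated correlation), with 1 member called, the death receptor TNFRSF10B, and 12 adjusted over the list alone. The ATF4 list was higher (adjusted p = 0.0164, adjusted p = 0.581 with an estimated correlation) with no member called either way of adjusting, over all genes or adjusted over the list alone.

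Macrophage and microglia markers lay below all tumours in 17 of 17 cases, against 16.7% by chance and 16.6% of all tested genes (0.05 against 2.33 ± 0.84, adjusted p = 2.61e-13), endothelial markers in 14 of 15 (adjusted p = 5.43e-09), pericyte and fibroblast markers in 10 of 15 (adjusted p = 2.56e-06), astrocyte markers in 7 of 10 (adjusted p = 0.00318) and red cell markers in 4 of 5 (adjusted p = 0.000145), each with adjusted p = 0.444 with an estimated correlation. Over all genes only HBB was called among them, as lower, and adjusted over the list alone 3, 1, 4, 2 and 3 were lower and 0, 0, 1, 1 and 0 higher. The extracellular matrix list was lower (1.31 against 2.80 ± 0.89, adjusted p = 8.94e-10, adjusted p = 0.444 with an estimated correlation), yet its 3 called members, SNAI1, FBN2 and LAMA1, were higher in D341, with 4 higher and 1 lower adjusted over the list alone. Neuronal structure genes were lower (adjusted p = 3.31e-08, adjusted p = 0.444 with an estimated correlation), with NEFH higher and MAP2 lower by either adjustment, over all genes or adjusted over the list alone. The interferon list was lower (adjusted p = 0.000139, adjusted p = 0.444 with an estimated correlation), with BST2, which tethers virus particles, the 1 member called and higher, and 3 higher and 1 lower adjusted over the list alone. Photoreceptor genes were lower (median -0.87, adjusted p = 0.00318, adjusted p = 0.581 with an estimated correlation), with ISL2 and ASMT called and higher by either adjustment, over all genes or adjusted over the list alone, and the list's call was lost without tumour 4 (adjusted p = 0.566), with quantile normalization (0.179) and with no filter (0.0841), over a range of 0.00012 to 0.566 in 10 alternatives. Axon guidance genes tested as lower only relative to other genes (camera adjusted p = 0.0378, adjusted p = 0.444 with an estimated correlation). Their mean log2(FPKM + 1) was 1.6 in D341 and 1.61 ± 0.209 in the tumours, with 16 members above and 17 below all tumours. EFNA4 was called and higher, and 2 were higher and 1 lower adjusted over the list alone. The list's call was lost without tumour 2 (adjusted p = 0.0549) or tumour 5 (0.0709), with quantile normalization (0.322) and with no filter (0.293), over a range of 0.0182 to 0.322. Neural and retinal factors had adjusted p = 0.0441 as lower (adjusted p = 0.444 with an estimated correlation), a negative mean (-0.05) and a positive median (0.03), no member called either way, and no call without tumour 1 (adjusted p = 0.0883), tumour 2 (0.0607) or tumour 3 (0.0536), with a pseudocount of 0.1 (0.107) or with quantile normalization (0.444).

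Replication-dependent histones tested as lower (mean -1.25, adjusted p = 4.12e-05, adjusted p = 0.581 with an estimated correlation) while their median was 0.35, and small structural RNAs as lower (adjusted p = 0.00329, adjusted p = 0.516 with an estimated correlation). No member of either was called over all genes or adjusted over the list alone. Glycolysis (adjusted p = 0.13, which became 0.0199 without tumour 2 and 0.0364 with no filter), Notch (0.1, and 0.0311 with quantile normalization), Polycomb (0.747, with median and mean above 0 and the test lower), Group 3 (0.937), oligodendrocyte (0.525) and granule and Purkinje neuron lists (0.238) did not pass the threshold. In these 6 lists 0, 1, 0, 0, 0 and 0 members were called, the 1 being HMGA2, higher in D341, and 1, 4, 0, 0, 1 and 0 were higher adjusted over the list alone. Of the lists too small to test, PDLIM3 of the SHH markers was called, higher in D341 by both counts, while the WNT, Group 4 and lymphocyte lists had no call over all genes or adjusted over the list alone.

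**Figure D4:**
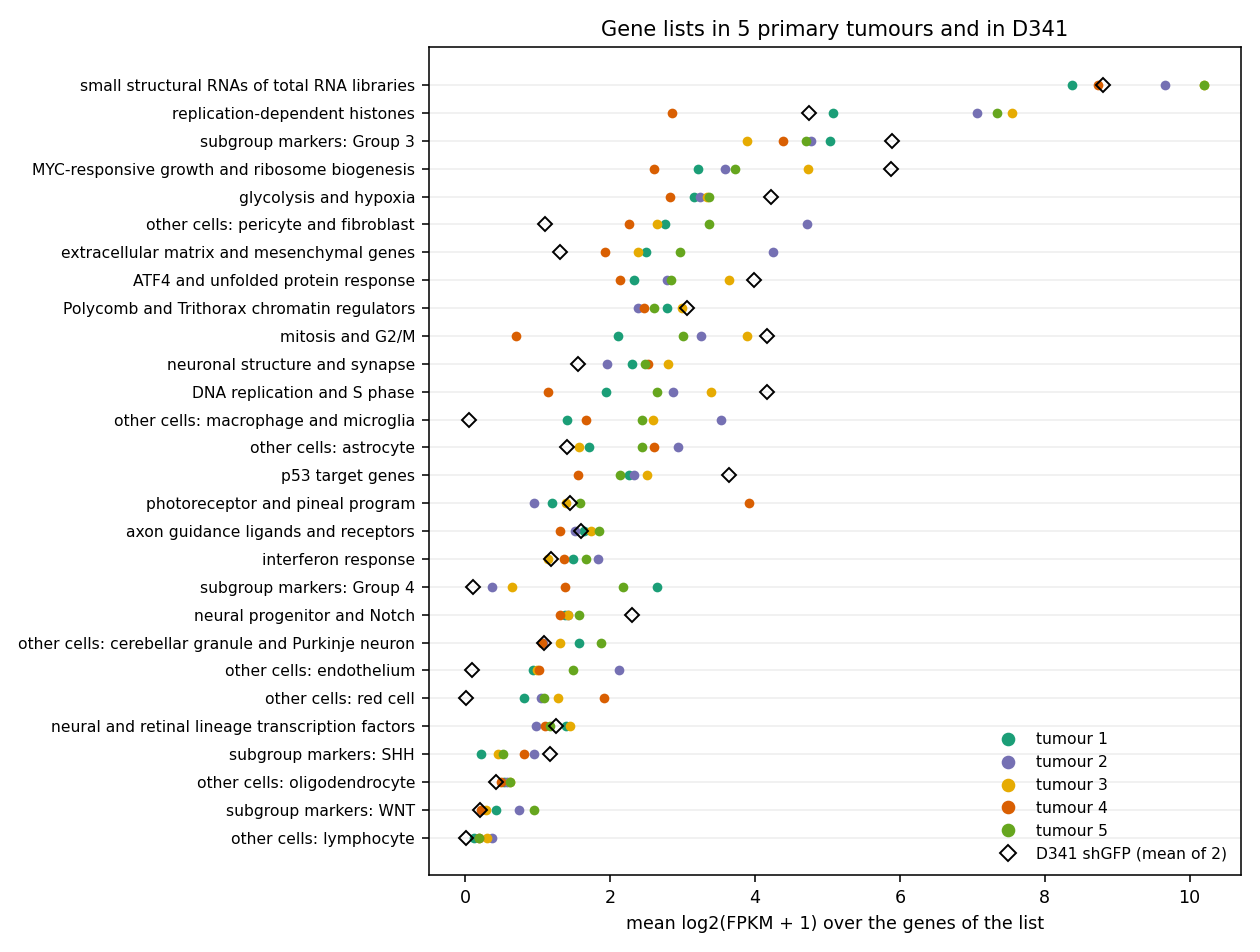
Mean log2(FPKM + 1) of each gene list in each tumour (coloured points) and in D341 (diamonds, mean of 2 shGFP libraries). D341 lies above the tumours for MYC-responsive growth (5.87) and below them for macrophage markers (0.05), and tumour 4 lies above the other tumours for photoreceptor genes (3.92).

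Genes were tested with limma and lists with camera, which called 18 of 24 lists, 5 higher and 13 lower in D341. Camera compares a list with all other tested genes, so a list called lower can also be one that rose less than they did. With an estimated correlation none passed and 1 had an unadjusted p under 0.05, a setting with little power at so few residual degrees of freedom. The median difference over all tested genes was 0.54 on the log2 scale, and with quantile normalization (median 0.01) 76 genes were higher and 16 lower. RMRP, RPPH1 and all symbols of small RNA, microRNA, LOC or clone style together took 47.7% to 66% of summed FPKM in the tumours. In the D341 shGFP libraries they took 33.9% and 33.1%. These are not shares of small RNAs alone, since LOC and clone-style symbols can be long RNAs. The count of 149 fell to 52 higher and 0 lower without tumour 1, 51 and 0 without tumour 5, 93 and 2 without tumour 2 and 85 and 7 without tumour 4, and rose to 242 and 17 without tumour 3, at 2092, 2137, 2421, 2521 and 4006 genes with an unadjusted p under 0.05. Of 29 named genes called, 7 kept the call whichever tumour was left out and 22, 16, 7, 18 and 20 lost it without tumours 1 to 5. BEX4 was lost without tumours 1 and 5 (adjusted p = 0.0651 and 0.0622), and BEX2 without tumours 1, 2 and 5 (0.103, 0.0858 and 0.0786).

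The last comparison asked whether genes that changed in D341 with the hairpin against OTX2 are expressed in the tumours. Genes that fell by at least 2-fold after depletion were 853, of which 442 (51.8%) reached 1 FPKM in at least 3 tumours, and genes that rose by at least 2-fold were 796, of which 378 did (47.5%), against 76.1% of all 13592 genes tested. Relative to random lists matched on their level in D341, the genes lower after depletion had a median log2(FPKM + 1) that differed by -0.47, -0.03, -0.28, -0.40 and -0.20 in tumours 1 to 5, a mean of -0.28 ± 0.17 (SD, n = 5; exact 2-sided sign-flip permutation p = 0.0625, the smallest that 5 tumours allow). The genes higher after depletion differed by 0.16, 0.08, -0.16, 0.27 and -0.05, a mean of 0.06 ± 0.17 (exact permutation p = 0.4375). The higher list exceeded the lower one by 0.34 ± 0.29 (exact permutation p = 0.0625). Photoreceptor genes, picked after the values were seen, show how tumours differed. PDE6A and ABCA4, both lower after depletion, were at 36.8 and 26.9 FPKM in tumour 4 and at most 0.35 and 6.23 in the others. The direction of both lists held without each tumour, but the mean of the higher list dropped to 0.00815 without tumour 4 and was 0.115 without tumour 3. The sizes depended on the matching, since lists matched on the shGFP libraries alone differed by -0.58 for the lower and 0.26 for the higher genes. They also depended on the genes taken, since all called genes gave -0.143 for the lower list (exact permutation p = 0.4375) and 0.28 for the higher list (exact permutation p = 0.0625).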

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

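Of 88 values looked at across the 5 tumours, those of genes below 1 FPKM in every tumour were passed over without a test. Among the rest, 4 stood apart from the other 4 tumours by Dixon's rule, with a gap over range above the critical value of 0.71. Chance flags about 1 in 20 tested groups. Photoreceptor and pineal genes had a mean log2(FPKM + 1) of 3.92 in tumour 4 and of 0.95 to 1.58 in the others (gap over range 0.788). EYA1, a transcription cofactor, was at 1.67 in tumour 5 and 0.159 to 0.47 elsewhere (0.794). SFRP1, a secreted WNT antagonist, was at 2.68 in tumour 4 and 0.013 to 0.709 elsewhere (0.739). FBN2, a fibrillin, was at 1.35 in tumour 5 and 0.222 to 0.333 elsewhere (0.902). For EYA1, SFRP1 and FBN2 the cause was not tested.

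Of the tests on tumour 4, those of FPKM scale and retina tissue were planned before the result was seen, and that of dilution was chosen only afterwards. Of 56 photoreceptor and pineal genes 40 were highest in tumour 4, with RCVRN at 235.7 FPKM, SAG at 104.1, NRL at 128.7 and the cone transducin subunit GNGT2 at 51.11, although the cone genes GNAT2 (0.365), ARR3 (0.34) and PDE6C (0.149) were low, and its mitosis list mean was 0.70. An FPKM scale effect is unlikely, as the gap over range was 0.86 after quantile normalization (5.18 against 1.14 to 1.71). Dilution by the cell types of the 8 other lists is less likely, as only 1 of these lists was highest in tumour 4. None of the 8 lists covers retinal or pineal cells, so this test cannot exclude such tissue. Retina tissue in the sample remains a candidate explanation: markers of other retinal cells had a mean of 0.815 against 0.115 to 0.391, but this rests largely on CABP5 at 44.3 FPKM, and RLBP1 of Müller glia was listed at 0. A photoreceptor-like state of the tumour cells could also give these values. Protein staining of NRL with a proliferation marker on a section of the tumour might help to separate the 2 explanations. It need not decide, since with so low a mitosis list mean NRL-positive tumour cells could lack the marker too.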

How the results depend on the processing

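Genes called in D341 (5288) numbered 3465 and 3315 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), 3447 at an adjusted p under 0.01, 1649 at a log2 fold change of at least 1, and 2276 to 5105 without 1 library. Lower genes (2812) numbered 1849 at 0.01, 853 at a change of at least 1 and 1333 to 2677 without 1 library; higher genes (2476) numbered 712 and 675 with limma on FPKM, 1598 at 0.01, 796 at a change of at least 1 and 943 to 2428 without 1 library. A replicate term gave 5514 called genes. OTX2 was at -0.56 with either FPKM fit (adjusted p = 0.157 and 0.15) and at -0.41 to -0.30 without 1 library. CRX changed sign with upper-quartile normalization (0.0058) and with the filter of at least 1 CPM (0.0072) and ranged from -0.24 to 0.24 without 1 library, and MYC was at -0.146 and -0.1463 in the FPKM fits and at -0.042 to 0.14 without 1 library. Of the 20 lists in D341, 0 were called with an estimated correlation and 1 with fry. Lists far from the threshold changed direction: extracellular matrix with the filter of at least 1 CPM (adjusted p = 0.929), Group 3 with upper-quartile normalization (0.987) and no filter (0.985), and pericyte with RLE (0.991), upper-quartile normalization (0.987), the filter of at least 1 CPM (0.816), the replicate term (0.999), fry (0.928) and without small RNAs, ribosomal proteins and MALAT1 (0.982). Without 1 library the lists with changed directions had adjusted p of 0.0841 to 0.813 for p53 targets, 0.498 to 0.979 for Notch, 4.23e-08 to 0.369 for extracellular matrix, 0.607 to 0.961 for Group 3 and 0.000808 to 0.813 for pericyte. Against the tumours, the 149 genes called became 464 with no filter, 3179 with the 2 control libraries as 2 samples, 92 with quantile normalization (76 higher, 16 lower) and 51 to 259 without 1 tumour, and 0 lists were called with an estimated correlation. A pseudocount of 0.1 called 169 genes but turned the balance, from 139 higher and 10 lower to 42 and 127. HHIP changed sign with a pseudocount of 0.1 (0.18) and quantile normalization (0.025), and NRL with quantile normalization (-0.085). Without 1 tumour TNC ranged from -0.92 to 0.022, HHIP from -0.39 to 0.013 and EYS from -0.42 to 0.038. Lists with a changed direction were neural and retinal factors with no filter (adjusted p = 0.552), Polycomb with a pseudocount of 0.1 (0.997) and no filter (0.592), Group 3 with quantile normalization (0.777; 0.664 to 0.845 without 1 tumour) and oligodendrocyte with quantile normalization (0.794). In the tumours, genes changed by the OTX2 hairpin differed, when matched on shGFP, by -0.576 (lower list) and 0.255 (higher list), and by -0.143 and 0.28 with every called gene. Shares expressed were 63.3% and 61.4% at 0.5 FPKM and 21.1% and 14.7% at 5 FPKM for the lower and higher lists. Apart from leaving out a library, named calls in D341 were lost with limma on FPKM for OTX2, NPR3, EYS, GABRA5, SMARCA2, RMRP, SNORD17 and SCARNA7, with DESeq2 for NRL, SFRP1, VWF, TAGLN, PDGFRB and UGT8, and with upper-quartile normalization for NRL and RMRP. Against the tumours they were lost with a pseudocount of 0.1 for SLC13A4, MGST1, ISL2, ASMT, EFNA4, TNFRSF10B, BST2, HMGA2, SNAI1, FBN2, LAMA1 and PDLIM3, with quantile normalization for all of these but SNAI1 and for RPS16, HBB, NNAT, MAP2 and CLIP4, and with no filter for MGST1, HBB, ASMT, TNFRSF10B, BST2 and PDLIM3. Over all results, named genes in D341 kept their result in 1493 cases, were weaker in 55 and changed sign in 8, and lists did so in 194, 21 and 16, with 8 stronger. Against the tumours genes did so in 303, 117 and 6 cases and lists in 224, 30 and 6, with 3 stronger. Leaving out small RNAs, ribosomal proteins and MALAT1, and leaving out genes listed at 0 despite counts, were alternatives chosen after seeing the data. The limma fit on log2(FPKM + 1) had a median log2 fold change over all genes of -0.192, against -0.0171 in the main fit. There OTX2 was at -0.56 against -0.36 and MYC at -0.146 against 0.04. That fit called 2753 lower and 712 higher genes, against 2812 and 2476 in the main fit. The shift of scale can thus account for part of the changes with FPKM. For the other differences the cause was not tested. With 2 libraries per group a 1.5-fold change was recovered for 42% of simulated genes. That simulation changed 200 genes, far fewer than the 5288 called, so the rate need not hold here. Genes with a few reads, such as GFI1 and EOMES, cannot be compared at this depth.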

Other observations

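Genes were also grouped by the stem of their symbols after the values of OTX2 depletion were seen. Of 151 such families camera called 11, 6 higher and 5 lower, and none with an estimated correlation (adjusted p = 0.967 with an estimated correlation for each of the 11, and 1 family at an unadjusted p under 0.05). As for the lists, that setting has little power here. Clustered protocadherins, adhesion molecules that give neurons surface identity, rose: 14 of 16 PCDHB genes (median 1.23, adjusted p = 5.08e-06), 9 of 10 PCDHGA genes (1.48, adjusted p = 0.00308) and 9 of 10 PCDHA genes (1.62, adjusted p = 0.00562). Of 469 ZNF zinc finger genes, many of them repressors, 170 rose and 17 fell. Bitter taste receptor genes rose in 10 of 11 cases (1.45, adjusted p = 0.00757), and CACNA calcium channel genes in 6 of 11 with 1 lower (0.43, adjusted p = 0.0407). The 5 lower families were HIST histones (39 of 40 genes lower, adjusted p = 4.15e-34), MCM genes (8 of 10 with 1 higher, adjusted p = 0.000144), COL collagens (11 of 26 with 4 higher, adjusted p = 0.0135), EEF elongation factors (6 of 10, adjusted p = 0.0145) and MRPL mitochondrial ribosomal proteins (16 of 50, adjusted p = 0.0404).

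Of the tests on the neuronal genes, that of transcript length was planned before the result was seen and that of nuclear RNA was chosen only afterwards. Neuronal structure genes rose by a median of 1.06, and length is an unlikely cause, since the median was 1.11 after the trend on transcript length was removed. More nuclear RNA in the shOTX2 libraries may contribute. The 7 RNAs taken as markers of the nucleus had a median of 1.36 (SE 0.6), and 5 of them rose, MALAT1, NEAT1 and MIAT among them. Their wide range, from OIP5-AS1 to MIAT, leaves a nuclear excess possible rather than shown. Whether each of the 7 stays in the nucleus was not tested. Small nucleolar RNAs did not share the rise. Of 57 SNORA genes 12 fell and 0 rose (median -0.392), and of 16 SNORD genes 4 fell and 0 rose (median -0.415). Neither family was called. Of 17 SCARNA genes 4 rose and 1 fell. Counting intronic against exonic reads in the same libraries could separate a nuclear excess from neuronal differentiation.

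Of the tests on the size of the response, that of depth was planned before the result was seen and those of cell share and of the hairpin were chosen only afterwards. OTX2 RNA fell by 22.2% while 5288 genes changed, and 4441 of these changed more in shOTX2 library 1 (median 0.812 on the log2 scale) than in library 2 (0.602), although OTX2 was at 805 CPM in library 1 and 736 CPM in library 2. Loss of OTX2 in a small share of cells is unlikely, as 181 genes fell by 4-fold or more, and deeper control libraries are unlikely too, as counts thinned to 1 depth still called 5029 genes. An off-target effect of the hairpin could explain part of the response and stays open, because 1 hairpin against OTX2 was used. A partial loss of OTX2 protein beyond its RNA might also do so, which a protein blot and a hairpin of another sequence would test.

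For neighbouring genes, the test around MYC was planned before the result was seen and that around BEX2 was chosen only afterwards. The mean difference of the 20 neighbours of MYC lay at percentile 44.1 of all windows, so a gain of all 20 is an unlikely source of its level in D341. A shorter gain was not tested, because a mean of 20 genes cannot show it. Beside MYC, CASC21 (1.91 FPKM in D341), CASC11 (1.43) and PVT1 (4.03) exceeded the highest tumours (0.382, 1.02 and 3.8). PHF20L1, farther away, stood at 171 FPKM against a tumour mean of 7.24. Of the 20 neighbours 6 were above all tumours and 4 below, against 43.5% and 16.6% of all tested genes. The 20 neighbours of BEX2 lay at percentile 0.273, but BEX4 and TCEAL7, themselves part of the pattern, are among them, so this value does not decide whether a silenced or lost stretch lowers these genes. Of the other 18 neighbours 10 were below all tumours, against 16.6% of all tested genes, and 8 were not. In D341 those 8 were TCEAL8 (21.4 FPKM), TCEAL9 (12.8), BEX3 (51.1), TCEAL4 (14.5), TCEAL1 (4.5), MORF4L2 (108), LINC00630 (1.7) and TMSB15B (4.36). Expression of these 8 genes argues against loss of the whole stretch, while silencing or loss of parts of it stays open.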
